A study of Mus musculus with 6 samples.

How the data were processed

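RNA from basal keratinocytes of mouse ear epidermis was sequenced in 6 libraries, 2 each from intact males, females and castrated males of the CD1 stock. Per the labels' protocols, living cells positive for integrin alpha 6 and negative for CD34 were sorted by flow cytometry, which keeps basal cells of the interfollicular epidermis and leaves out the hair follicle bulge. Each library held polyA RNA of 100000 cells from 2 mice of 1 litter. The 2 libraries of a group therefore stand for 2 pools, p-values measure the spread between pools, and the litter of a pool cannot be separated from its sex or treatment.

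Per the submitters' processing notes, the authors used FastQC, STAR 2.7.5a, Picard and HTSeq 0.11.1 with the builds GRCm38 and mm10. The annotation, the strand setting of the counting and the scaling of the table are not given in the sources used here. The deposited table lists 49671 Ensembl genes with 1 column per library. As deposited, each value is a score: read counts per gene had been scaled in each library to a total of 20000000 and rounded before deposit. Within a column the scores are whole multiples, after rounding, of 1 step between 2.07 and 2.38. In every library 100.0% of the values lay within 0.5, the error of rounding, of a multiple of that step, which 42.1% to 48.2% of arbitrary whole numbers do. Dividing by the step gave whole reads, with totals from 8412487 (female replicate 2) to 9648154 (female replicate 1). On simulated columns of 49671 genes, scaled and rounded in the same way, the step search returned the reads of 100.0% of genes. Because the deposited columns are not counts, the negative binomial test planned before the data were examined was replaced by limma on a log scale. The recovered reads could have entered the planned test, which was not run. The library of the second male sample carries the number 3 in its name and the number 2 in its title, and the title was used.

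Library sizes were adjusted with TMM factors, a trimmed mean of log ratios computed on the recovered reads, which ran from 0.927 (female replicate 2) to 1.03 (castrated male replicate 1). Values are CPM, reads relative to library size, after this scaling. Genes with a CPM worth 10 reads at the median depth (1.16 CPM) in at least 2 libraries and at least 15 reads in total were tested, 15413 in all. Tests used log2(CPM + 0.5) in limma 3.58.1 (R 4.3.3), with 1 mean per group, all 6 libraries in 1 fit, 3 residual degrees of freedom and an intensity trend in the prior variance (prior degrees of freedom 5.82). Adjusted p-values are Benjamini-Hochberg values within a comparison, a gene was called at an adjusted p below 0.05, and all p-values are two-sided. Fold changes are on the log2(CPM + 0.5) scale and understate the change of genes with few reads. One read was worth 0.104 to 0.119 CPM, and 3 reads, the limit that a count of 0 allows, 0.311 to 0.357 CPM in a library. Such limits cover counting error only.

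The 3 groups were compared in pairs. A total of 42 gene lists on the sex chromosomes, hormones, epidermal layers, cellular processes and 11 sets of other cell types were fixed before the data were examined, and 37 with at least 5 measured members were tested with camera in limma (preset correlation of 0.01). The camera test was repeated with an estimated correlation, and fry was run beside it. With an estimated correlation camera rests on the 3 residual degrees of freedom of the fit, so it had little power to call any list. A call lost in this way counts neither for nor against a list. For called lists, counts of members are given over all genes tested and adjusted over the list alone. The shared direction of both comparisons with intact males was set beside 100 simulations with unchanged groups and the same males. The groups, the comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule a comparison names the measured sex chromosome list genes and the 8 largest changes in each direction among called genes with a mean of at least 5 CPM, no overlap of the groups and an established symbol. The rule adds up to 4 members with the smallest p of each list described, and 14 genes of hormone response, basal cells and sorting in every comparison, and not every gene it names is described. Other genes are said to have been chosen after their values were seen.

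The whole procedure was tested on simulated data with 200 changed genes and 10 draws per comparison. With gene spreads drawn from the fitted prior, the simulation of females against males (15321 genes) recovered 38% of 2-fold and 80% of 4-fold changes, with 5.4% false among all calls. The shares were 44.1% and 81.2% with 5% false for castrated against intact males (15314 genes), and 40.5% and 79.5% with 5.5% false for castrated males against females (15313 genes). An earlier form of the simulation used the fitted spreads themselves and recovered 60%, 59.7% and 59.8% of 2-fold changes, with false shares of 9.6%, 8.3% and 9.1%, in the same order. Both forms drew noise independently for each gene, with the same spread in every library. In the real libraries genes vary together and single libraries stand apart, so the false shares may not hold for the calls below. Gene positions, types and transcript lengths came from GENCODE M21 on GRCm38, in which 49412 gene IDs had an entry and 259 had none. Near-identical copies of called genes were searched among transcripts with BLAST+ 2.17.0 (at least 95% identity over at least 100 bp). Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for the remaining steps. The alternatives covered scaling, the filter on low values, the tool, the libraries in the fit, a replicate block, the threshold, each library left out in turn and the genes counted, and, added after the data had been seen, the pseudocount, the transcript length trend and protein-coding genes alone.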

Results

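The study asked how sex and castration relate to gene expression in the stem and progenitor cells of the skin. Basal keratinocytes of the interfollicular epidermis were sorted from the ears of intact male, female and castrated male CD1 mice, an outbred stock, with 2 libraries per group and 2 mice of 1 litter in each library. The libraries held 9265207 and 8466450 reads in males, 9648154 and 8412487 in females, and 8521741 and 8675809 in castrated males. All values below are CPM as mean ± SD with n = 2 libraries per group, fold changes carry standard errors on the log2 scale, and adjusted p-values are from limma unless camera is named. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 12.9 in males, 13.6 in females and 4.79 in castrated males. The first principal component held 56.2% of the variance and placed the females (28.92 and 64.17) apart from the males (-21.21 and -32.39) and castrated males (-22.9 and -16.58). The second component (18%) set male replicate 1 (41.88) apart from the other 5 libraries (-15.67 to 1.74).

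Transcripts of the sex chromosomes followed the sample labels. Ddx3y, Eif2s3y, Kdm5d and Uty, single-copy genes of the Y chromosome, had 341 to 1937 reads in each intact and castrated male library and 0 to 2 reads in each female library. Xist, the RNA that silences an X chromosome, stood at 180 ± 39.3 CPM in females, 0.336 ± 0.0233 in males and 0.740 ± 0.241 in castrated males. Its antisense partner Tsix followed it (48.0 ± 12.4 in females), and reads of the overlapping pair cannot be told apart if the counting ignored strand. Of the 11 listed X genes, Xist, Tsix, Kdm5c, Ddx3x and Eif2s3x rose in females against males (5 called, 8 adjusted over the list alone, median log2 fold change 0.52, camera adjusted p = 4.83e-06). The camera call was lost with adjusted p = 0.476 with an estimated correlation, while fry called the list (adjusted p = 0.00097).

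Genes of activated keratinocytes and of mitosis were higher in females than in males. S100a8 and S100a9, which encode the subunits of calprotectin, stood at 398 ± 316 and 204 ± 180 CPM in females and at 0.443 ± 0.127 and 0.320 ± 0.452 in males (log2 fold changes 8.46 ± 0.49 and 7.73 ± 0.63, adjusted p = 0.000115 and 0.000866). Of 35 G2 and mitosis genes, 32 rose in females, with a median log2 fold change of 1.22. Of 24 basement membrane and 17 circadian clock genes, 7 and 7 fell, with medians of -0.58 and -0.68. Camera called these 3 lists, none of them with an estimated correlation (adjusted p = 0.476), and without female replicate 2 they held 0, 0 and 1 called genes. In all, 940 of 15413 genes were called, 571 higher and 369 lower in females, and 568 of them changed by at least 2-fold. Of these genes 35 lie on X and 5 on Y, which leaves 900 elsewhere.

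Among the other genes with the largest rise in females were BC100530 (329 ± 213 against 3.58 ± 0.248 CPM, adjusted p = 0.000586), BC117090 (84.9 ± 60.8 against 0.938 ± 0.330, adjusted p = 0.00147) and Stfa3 (122 ± 89.4 against 3.48 ± 0.557, adjusted p = 0.00382). All lie on chromosome 16, in the cluster of stefin A genes, which encode inhibitors of cysteine proteases. Because members of this cluster resemble each other, the division of reads between them is uncertain. Sprr2d, a precursor of the cornified envelope, rose to 110 ± 122 from 3.70 ± 4.56 CPM (adjusted p = 0.0374), Car2, a carbonic anhydrase, to 42.8 ± 16.7 from 1.41 ± 0.335 (adjusted p = 0.00115), and Klk13, a kallikrein-related peptidase, to 36.9 ± 24.4 from 1.11 ± 0.239 (adjusted p = 0.00382). Outside the sex chromosomes the largest fall among called genes was that of Ogn, an extracellular matrix proteoglycan, from 63.2 ± 6.61 CPM in males to 2.65 ± 3.20 in females (log2 fold change -4.86 ± 0.65, adjusted p = 0.00862). Baiap2l1, which encodes a protein that shapes actin-rich membranes (chromosome 5, 144264526 to 144358112 in GRCm38), fell from 511 ± 189 to 26.6 ± 8.56 CPM (adjusted p = 0.000472). Stag3, a cohesin subunit of meiosis, fell from 10.7 ± 0.896 CPM to 0.115 ± 0.0184, below what 3 reads are worth, and Gpc2, a glypican on the same chromosome, from 15.4 ± 1.31 to 1.83 ± 0.593. Gucy1b3, Sncg, Ablim3 and Stk33 fell by log2 fold changes of -3.64, -3.35, -3.22 and -2.76, with adjusted p-values from 0.00884 to 0.0365. The mean of Sncg in males rests mainly on replicate 2 (134 CPM against 16.2 in replicate 1).

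**Figure D1:**
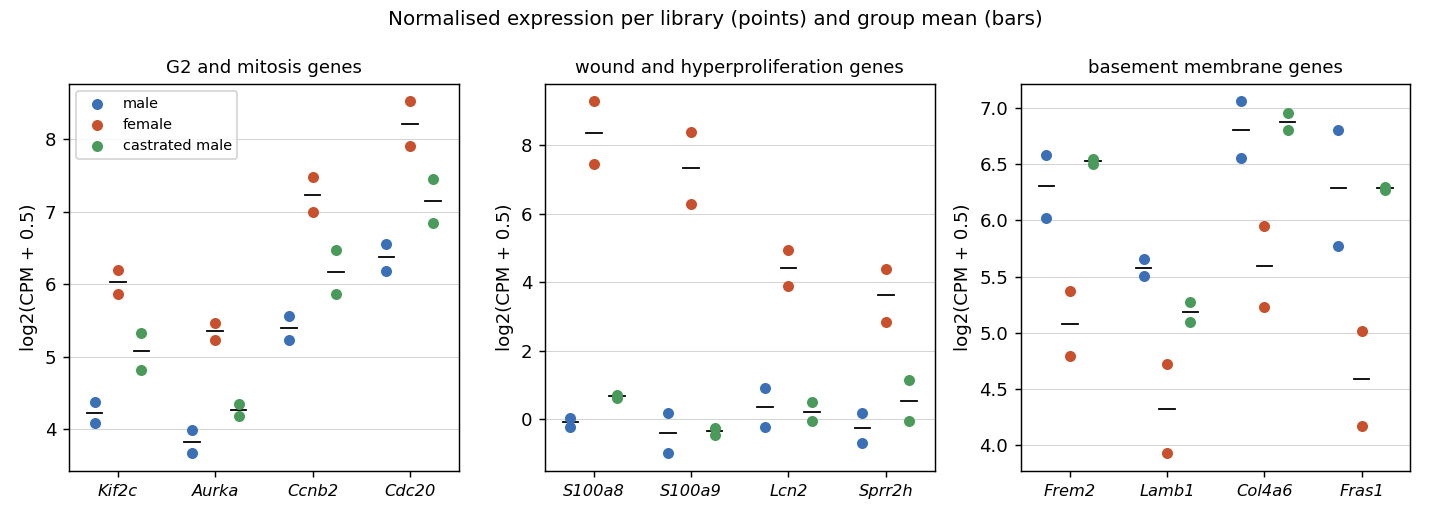
Expression of 4 genes each of the mitosis, wound and basement membrane lists, as log2(CPM + 0.5) on the vertical axis, with 1 point per library and a bar at the mean of each group (male, female, castrated male; n = 2). Both female libraries lay above all intact and castrated male libraries for the mitosis and wound genes and below them for the basement membrane genes.

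Camera called the lists of mitosis genes and of S phase genes higher in females. Kif2c, a microtubule-depolymerising kinesin of mitosis, stood at 65.4 ± 10.5 CPM in females and 18.3 ± 2.68 in males (log2 fold change 1.80 ± 0.21, adjusted p = 0.00523). Aurka, a kinase of the spindle pole, rose by 1.52 ± 0.19, Ccnb2, a mitotic cyclin, by 1.84 ± 0.23, and Cdc20, an activator of the anaphase-promoting complex, by 1.84 ± 0.25 (adjusted p = 0.0062, 0.00685 and 0.00884). Mki67, the gene of the proliferation marker Ki-67, rose by 0.86 ± 0.20 (adjusted p = 0.044). All 35 mitosis genes had a positive fold change, 32 were called and 33 were called adjusted over the list alone (camera adjusted p = 1.2e-25, adjusted p = 0.476 with an estimated correlation). Of 35 S phase and DNA replication genes 6 rose, Mcm10, Cdt1, Rrm1, Rrm2, Ung and Uhrf1, and 18 did adjusted over the list alone (median 0.51, camera adjusted p = 3.44e-10, adjusted p = 0.508 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, stood at 99.5 ± 31.1 CPM in females against 46.4 ± 4.16 in males.

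Keratinocyte genes of wounds and hyperproliferation had the largest median among the epidermal lists, 2.15 over 16 measured genes. Krt6a, Krt6b, S100a8, S100a9, Sprr1a, Sprr2d, Sprr2h, Tnc and Lcn2 rose and Il33, an alarmin cytokine, fell (276 ± 0.966 CPM in males, 141 ± 37.8 in females). That made 9 risen genes, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.86e-09, adjusted p = 0.476 with an estimated correlation). Lcn2, which encodes the iron-sequestering lipocalin, stood at 22.2 ± 11.2 CPM in females and 0.869 ± 0.730 in males. Krt16, also in the list, did not pass (476 ± 134 against 371 ± 19.2 CPM, adjusted p = 0.311). Of 29 granular and cornified layer genes 8 rose, among them Abca12, Cnfn, Rptn, Flg and Sprr1a, and Lce1m and Flg2 fell. The list alone gave 12 higher and 2 lower (median 1.03, camera adjusted p = 2.89e-06, adjusted p = 0.477 with an estimated correlation). Lce1m fell from 9.23 ± 1.90 to 1.55 ± 0.558 CPM, and Abca12, a lipid transporter of the skin barrier, rose from 11 ± 4.45 to 42.8 ± 19.1. Of 21 spinous layer genes Krt1, Krtdap and Ptgs1 rose and Dsg1a fell, with 7 higher and 3 lower adjusted over the list alone (median 0.29, camera adjusted p = 0.0541). Krt1 stood at 124 ± 26.2 CPM in females and 34.9 ± 8.58 in males (adjusted p = 0.00862), whereas Krt10 did not pass (222 ± 4.08 against 171 ± 24.7).

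The main markers of the sorted basal cells did not pass the test between the sexes. Krt5 stood at 12270 ± 1595 CPM in females and 10730 ± 1011 in males, Krt14 at 15510 ± 2726 and 13260 ± 183, Itga6 at 344 ± 37.0 and 371 ± 3.87, and Trp63 at 1715 ± 69.4 and 1668 ± 104, none past the threshold. Krt15 was at 7784 ± 2032 CPM in females and 12680 ± 2982 in males (adjusted p = 0.136). Cd34, the marker of the excluded bulge cells, stood at 2.33 ± 0.0310 and 2.27 ± 1.11 CPM. Of 24 basal keratinocyte genes 2 rose, among them Cd44, and 2 fell, among them Sparc, while 3 rose and 12 fell adjusted over the list alone (median -0.26, camera adjusted p = 0.0696). Markers of other cells moved with the wound and mitosis genes in part. S100a8, S100a9 and Cxcr2 rose among 5 measured macrophage and neutrophil markers, also adjusted over the list alone, and the first 2 are also in the wound list (median 2.38, camera adjusted p = 0.000262, adjusted p = 0.476 with an estimated correlation). H2-Aa, H2-Ab1, Cd74, Ciita and H2-DMa, genes of antigen presentation on major histocompatibility complex class II, rose among 19 Langerhans and dendritic cell markers, and 9 did adjusted over the list alone (median 0.60, camera adjusted p = 8.9e-05, adjusted p = 0.476 with an estimated correlation). Cd74 stood at 979 ± 532 CPM in females and 222 ± 19.2 in males, while Cd207, the langerin gene of Langerhans cells, stood at 6.12 ± 1.14 and 7.53 ± 1.31 (adjusted p = 0.568). The pan-leukocyte gene Ptprc stood at 3.14 ± 0.822 and 3.35 ± 1.58 CPM. The lists of T cells, innate lymphoid and mast cells, melanocytes, fibroblasts, and erythrocytes and Schwann cells were not called (camera adjusted p = 0.981, 0.981, 0.702, 0.332 and 0.474), with Mitf alone of their members called, lower in females. Merkel, endothelial and skeletal muscle markers had 1, 3 and 4 measured genes, none called, and no adipocyte or cartilage marker was measured.

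The glycolysis list was called higher in females by camera. Pfkl, Gapdh, Pgk1, Pgam1, Eno1, Ldha, Slc16a3, Pfkfb3 and Bnip3 were the 9 risen genes among 19, and Pfkm fell. Adjusted over the list alone, 16 rose and 1 fell (median 0.95, camera adjusted p = 4.65e-09, adjusted p = 0.476 with an estimated correlation). Slc16a3, a lactate transporter, stood at 68.3 ± 42.4 CPM in females against 8.53 ± 6.92 in males, and Pgk1 at 243 ± 87.8 against 91.4 ± 8.76. All 31 oxidative phosphorylation genes had positive fold changes, 9 of them called and 27 adjusted over the list alone (median 0.47, camera adjusted p = 2.3e-13, adjusted p = 0.477 with an estimated correlation). Among them Uqcrq and Ndufa4 rose by 1.01 ± 0.17 and 0.98 ± 0.20. Of 39 ribosomal protein genes 37 had positive fold changes, 0 rose by limma and Rpsa fell, also adjusted over the list alone (median 0.25, camera adjusted p = 6.5e-06, adjusted p = 0.657 with an estimated correlation). Transcript length moved with these groups: log2 fold changes between females and males correlated with length across 9655 genes (Spearman rho -0.196, genes not being independent), and within single libraries the deviations did so most in female replicate 2 (-0.264) and castrated male replicate 1 (0.25). NRF2 and glutathione genes (23 measured, Gsta4 called, 4 higher adjusted over the list alone, median 0.28, camera adjusted p = 0.00586) and cholesterol synthesis genes (24 measured, Ebp called, also adjusted over the list alone, median 0.13, camera adjusted p = 0.0457) were also called as lists, with adjusted p = 0.477 and 0.681 with an estimated correlation. Fatty acid synthesis genes were not (median 0.16, camera adjusted p = 0.33).

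The list of basement membrane and collagen genes was called lower in females by camera. Of 24 measured genes 7 were called, among them Col4a6, Lamb1, Fras1 and Frem2, and 1 rose and 12 fell adjusted over the list alone (median -0.58, camera adjusted p = 2.4e-05, adjusted p = 0.476 with an estimated correlation). Fras1 and Frem2, which anchor the epidermis to the dermis, stood at 24.7 ± 10.1 and 34.0 ± 9.70 CPM in females and at 82.6 ± 40.2 and 80.0 ± 21.9 in males. Of 17 circadian clock genes 7 fell, among them Npas2, Per1, Hlf and Ciart, 11 did adjusted over the list alone, and the median was -0.68 (camera adjusted p = 2.46e-07, adjusted p = 0.476 with an estimated correlation). Of 25 YAP and TEAD targets Ptpn14, Nt5e and Tgfb2 fell (8 lower and 1 higher adjusted over the list alone, median -0.23, camera adjusted p = 0.00586, adjusted p = 0.476 with an estimated correlation).

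Of the lists of hormone genes, the estrogen-responsive list was called between females and males. Srd5a1, which encodes a steroid reductase that makes dihydrotestosterone, stood at 23.6 ± 0.705 CPM in females and 33.6 ± 4.15 in males (adjusted p = 0.123). Esr1, an estrogen receptor gene, had 14.4 ± 0.837 CPM in females and 3.94 and 34.1 in the male libraries. Its log2 fold change of 0.27 became -1.2 without male replicate 1 (adjusted p = 0.0383) and 1.72 without male replicate 2 (adjusted p = 0.0215). Akr1c18, whose product inactivates progesterone, rose to 99.1 ± 21.8 from 23.7 ± 7.37 CPM (adjusted p = 0.00615), and the receptor genes Nr3c1 and Nr3c2, of glucocorticoids and mineralocorticoids, fell by log2 fold changes of -0.84 ± 0.14 and -1.70 ± 0.37. The list of steroid receptors and steroid-converting enzymes was not called (12 measured, median 0.06, camera adjusted p = 0.758). Of 42 androgen-responsive genes Steap4 rose and Tsc22d3 and Sord fell, also adjusted over the list alone (median -0.03, camera adjusted p = 0.676). Of 23 estrogen-responsive genes Myb, Celsr2, Abca3, Fos and Wnt4 rose, with 8 higher and 1 lower adjusted over the list alone (median 0.33, camera adjusted p = 0.00712, adjusted p = 0.476 with an estimated correlation). The fry test called the estrogen list (adjusted p = 0.0171).

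Of the signalling lists, those of EGF receptor signalling and of immediate early genes were called by camera. Tgfa, Erbb3, Epgn, Dusp6 and Etv4 rose among 16 genes of EGF receptor signalling, with 7 higher and 1 lower adjusted over the list alone (median 0.44, camera adjusted p = 0.0381, adjusted p = 0.519 with an estimated correlation). Tgfa, a ligand of the receptor, stood at 13.2 ± 7.09 CPM in females and 2.95 ± 0.190 in males. Of 24 immediate early and dissociation stress genes Fos, Junb, Egr1, Ier2, Ier3, Zfp36 and Hspe1 rose and Hspa1b fell. Adjusted over the list alone, 10 rose and 3 fell (median 0.45, camera adjusted p = 0.000356, adjusted p = 0.476 with an estimated correlation). Notch genes (15 measured, Jag1 called) were called by fry (adjusted p = 0.0171) but not by camera (adjusted p = 0.736). The lists of Wnt, TGF-beta and BMP, cell cycle inhibitor, interferon-stimulated, chemokine and alarmin, glucocorticoid-responsive, hair follicle and sebaceous gland genes were not called by camera, with adjusted p-values of 0.778, 0.103, 0.378, 0.736, 0.464, 0.234, 0.981 and 0.517 and medians of -0.12, -0.09, -0.11, -0.08, 0.21, 0.02, 0.01 and -0.11. In all, camera called 18 of 37 lists, 15 up and 3 down, of which 0 were called with an estimated correlation. That form of the test rests on 3 residual degrees of freedom. It gave adjusted p = 0.476 even for the X chromosome list, which fry called and whose estimated correlation was -0.0713. The lost calls therefore cannot be read as evidence against the lists. The fry test called 3 lists, 2 of them among the 18, and its mixed form, which asks for change in either direction, called 32.

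The number of genes called female against male depended on the libraries. Without female replicate 2, 49 genes were called, 47 of them among the 940, of which 891 could be tested. Without castrated male replicate 1 or 2, which enter through the shared spread, 204 and 271 were called, without male replicate 1 or 2, 646 and 539, and without female replicate 1, 1773. Of 89 named genes that were called, 18 stayed so whichever library was left out, among them BC100530, BC117090, Stfa3, Car2, Klk13, Ogn, Baiap2l1, Stag3, Gucy1b3, Gpc2, H2-Aa, H2-Ab1, Cd74 and the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty. S100a8, S100a9, Xist and Tsix were called wherever they were tested, but with 1 female library left out they did not reach the filter in the 2 libraries it asks for in at least 1 fit. Without female replicate 2 the mitosis list held 0 called genes (32 adjusted over the list alone, median 1.01), the wound list 2 (median 1.39), the cornified list 0 (median 0.56), glycolysis 0 (median 0.56), oxidative phosphorylation 0 (median 0.28), basement membrane 0 (median -0.4) and clock 1 (median -0.51). The S phase list then held 0 called genes, also adjusted over the list alone (median 0.36), as it did without male replicate 1 (median 0.40), and the cornified and estrogen lists 0 higher adjusted over the list alone. Without castrated male replicate 1 or 2, 0 and 0 members were called in the S phase, basement membrane, EGF receptor and estrogen lists, 1 and 1 in the oxidative phosphorylation, glycolysis and clock lists, 17 and 20 in the mitosis list and 4 and 5 in the wound list. Without male replicate 1 or 2 the mitosis list held 23 and 19, glycolysis 4 and 2, and oxidative phosphorylation 1 and 1. The cornified median was 1.63 without male replicate 1 and 0.66 without male replicate 2, and that of EGF receptor genes 0.28 without male replicate 2 and 0.25 without female replicate 2.

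List calls female against male ended for EGF receptor signalling and NRF2 genes without male replicate 2 (camera adjusted p = 0.193 and 0.0928), for estrogen-responsive genes without male replicate 1 (0.0529), and for cholesterol synthesis without male replicate 2, female replicate 2 or castrated male replicate 1 (0.298, 0.276 and 0.0548). The EGF receptor list also lost its call with no filter on low values (camera adjusted p = 0.0679). The macrophage and neutrophil list fell below 5 measured genes without either female library and was then not tested.

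**Figure D2:**
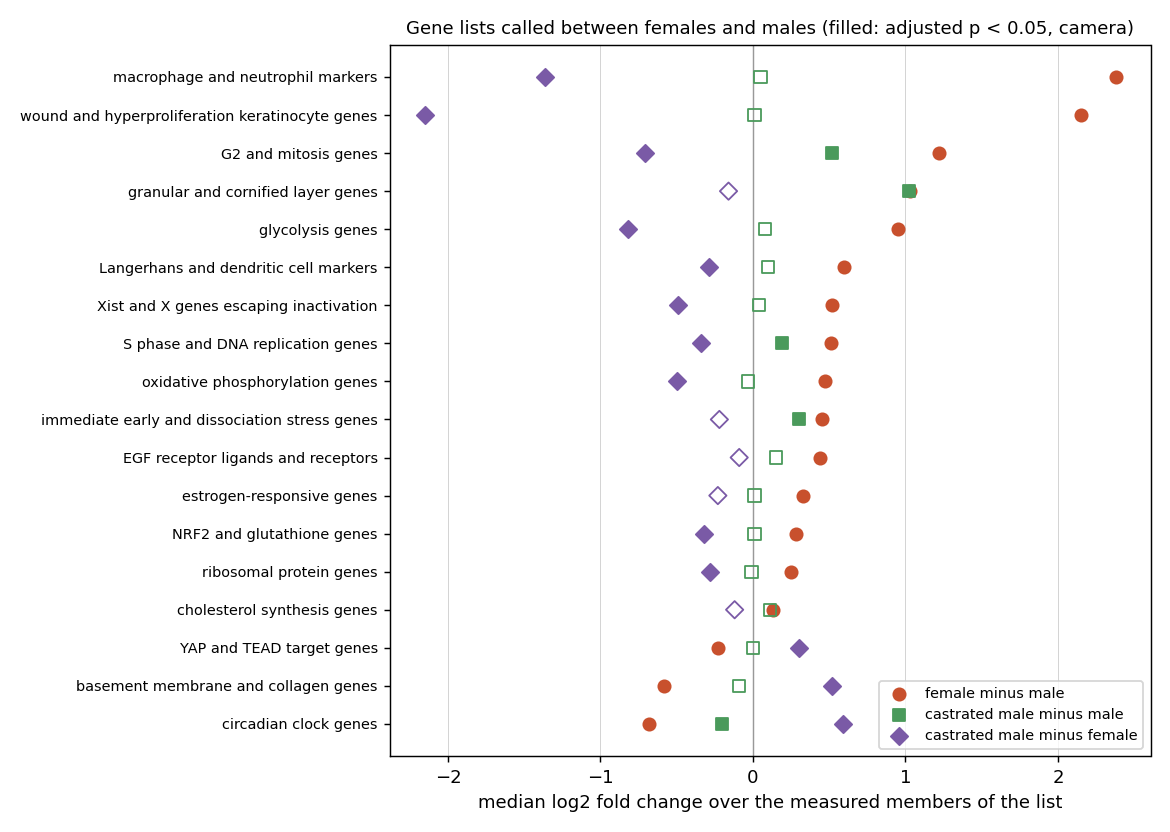
Median log2 fold change (horizontal axis) over the measured members of the 18 gene lists called between females and males, for the 3 comparisons (circles, squares and diamonds); filled symbols mark lists with a camera adjusted p below 0.05 in that comparison. The mitosis list had medians of 1.22, 0.52 and -0.71 for females minus males, castrated minus intact males and castrated males minus females.

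Castrated and intact males differed in few single genes. Ptgs2, the inducible cyclooxygenase gene, stood at 23.6 ± 3.88 CPM in castrated and 3.13 ± 0.0589 in intact males (log2 fold change 2.72 ± 0.21, adjusted p = 0.00439). Cox7b, a subunit gene of cytochrome c oxidase on X, rose from 83.1 ± 1.73 to 187 ± 2.44 CPM (adjusted p = 0.0107). Rpsa, a ribosomal protein gene, fell from 426 ± 17.8 to 167 ± 1.01 CPM (adjusted p = 0.0107), and Rps3a3 and Rps3a2, processed pseudogenes of Rps3a1, fell from 172 ± 10.4 to 2.90 ± 0.565 and from 23.6 ± 0.529 to 3.98 ± 0.0029 CPM (adjusted p = 4.3e-05 and 0.0111). The sixth called gene, the pseudogene Gm11222, stood at 5.61 ± 0.546 CPM in intact males, with 1 read in castrated male replicate 1 and 0 in replicate 2, and was named after its values were seen. In females it stood at 0.115 ± 0.0184 CPM. Summed with their copies, Cox7b and Rpsa stood at 218 ± 3.8 and 304 ± 31.4 CPM in females, against 83.5 ± 2.1 and 452 ± 26.5 in intact males. For these genes intact males thus stood apart from both other groups. Rps3a3 (163 ± 60.0 CPM in females) and Rps3a2 (183 and 229 reads in females, 218 and 204 in intact males) were low in castrated males alone. In all, 2 genes rose and 4 fell of 15413, and 914 had an unadjusted p below 0.05. Calls by limma-voom numbered 6, 3 higher and 3 lower, and included 5 of the 6 genes named here. Without castrated male replicate 1 or 2 only Rps3a3 was called in each case, and without male replicate 1 or 2, 28 and 74 genes were called. Rpsa, Rps3a2, Rps3a3 and Gm11222 have near-identical copies with reads in these libraries, so the division of reads between the copies is uncertain. The copies found for Cox7b held 0 to 9 reads per library.

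**Figure D3:**
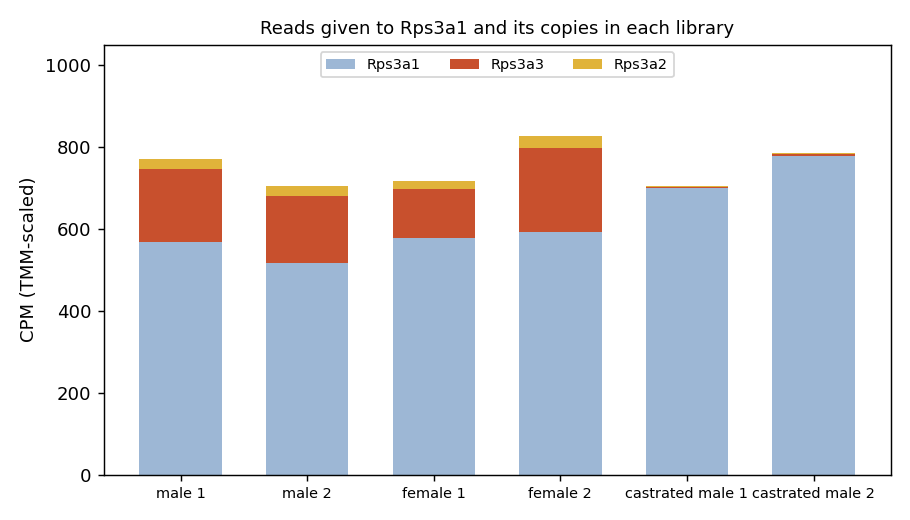
CPM (vertical axis) of Rps3a1 and its pseudogenes Rps3a3 and Rps3a2, stacked for each of the 6 libraries. The summed CPM of the 3 genes was 738 ± 45.8 in intact males, 772 ± 78.3 in females and 746 ± 56.7 in castrated males (n = 2).

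Camera called the mitosis and cornified layer lists upward in castrated males. All 35 mitosis genes had positive fold changes in castrated males with 0 called by limma, also adjusted over the list alone, and a median of 0.52 (camera adjusted p = 7.5e-20, adjusted p = 0.556 with an estimated correlation). Kif2c stood at 33.7 ± 8.39 CPM in castrated and 18.3 ± 2.68 in intact males, and Anln, a cytokinesis gene, at 129 ± 33.5 and 71.6 ± 5.75 (adjusted p = 0.517 and 0.425). Of 29 granular and cornified layer genes 27 had positive fold changes, 0 were called over all genes and 11 rose adjusted over the list alone (median 1.02, camera adjusted p = 8.7e-16, adjusted p = 0.556 with an estimated correlation). Crct1 stood at 21.7 ± 6.69 CPM in castrated and 7.97 ± 1.03 in intact males, and Flg2 at 19.4 ± 1.22 and 8.49 ± 1.55 (adjusted p = 0.24 and 0.545). Without male replicate 2 the cornified median of castrated_male against male was 0.49, and without castrated male replicate 2 the mitosis median was 0.32. The S phase (median 0.19), spinous (0.13) and immediate early genes (0.30) also had camera calls upward (adjusted p = 4.49e-05, 0.00475 and 0.00832), and the hair follicle (-0.15), sebaceous gland (-0.18), interferon-stimulated (-0.17), chemokine and alarmin (-0.31), clock (-0.20) and glucocorticoid-responsive genes (-0.37) downward (adjusted p = 0.00563, 0.0249, 0.00563, 0.0158, 0.0349 and 0.00299). These 9 lists had 0 called members each by limma (3 higher of the immediate early, 2 lower of the hair follicle, 1 lower of the sebaceous and clock lists, and 1 higher and 1 lower of the chemokine list adjusted over the list alone, and 0 in the others) and adjusted p = 0.556 or 0.607 with an estimated correlation. Without male replicate 1 the calls of the S phase, hair follicle, sebaceous (median then 0.01), interferon, chemokine, clock and glucocorticoid lists ended, without male replicate 2 those of the spinous, immediate early and clock lists, without castrated male replicate 1 that of the sebaceous list, and without castrated male replicate 2 those of the spinous, chemokine, immediate early and clock lists. Of the 11 lists called by camera 0 were called with an estimated correlation and 0 by fry (1 by the mixed fry test).

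Androgen-responsive genes were not called after castration: 0 of 42 passed, over all genes or adjusted over the list alone, with a median of 0.00 (camera adjusted p = 0.284). Fkbp5 stood at 16.4 ± 3.77 CPM in castrated and 28.0 ± 7.15 in intact males, and Tsc22d3 at 400.4 ± 47.1 and 715 ± 149 (adjusted p = 0.752 and 0.776). Srd5a1, Krt5, Krt14, Krt15 and Itga6 had log2 fold changes between -0.04 and 0.10, none past the threshold. Esr1 had a log2 fold change of -0.75 ± 0.74, which was -2.22 without male replicate 1 (adjusted p = 0.0182) and 0.73 without male replicate 2 (adjusted p = 0.431). Akr1c18 stood at 5.58 ± 0.962 CPM in castrated and 23.7 ± 7.37 in intact males, just above the threshold (log2 fold change -1.97 ± 0.25, adjusted p = 0.0527), and Krt79, a keratin of the hair follicle infundibulum, at 78.8 ± 16.1 and 163 ± 14 (adjusted p = 0.0925). Wound genes had a median of 0.01 (camera adjusted p = 0.848), basement membrane genes -0.09 (0.0679), oxidative phosphorylation genes -0.03 (0.698), glycolysis genes 0.08 (0.377) and ribosomal protein genes -0.01 (0.698). The remaining lists were not called either, with camera adjusted p-values between 0.103 and 0.938. In the simulation of this comparison 44.1% of 2-fold changes were recovered (59.7% in its earlier form), so changes of that size can be missed here. That simulation held 200 changed genes, whereas 6 genes were called here. With fewer changed genes the adjustment of p-values is stricter, so the share recovered here may be lower. Akr1c18, at a log2 fold change of -1.97, was itself not called.

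Castrated males and females differed in wound, stefin and chromosome 5 genes that were also called between females and intact males. S100a8 stood at 1.08 ± 0.0813 CPM in castrated males, a log2 fold change of -7.71 ± 0.49 against females (adjusted p = 0.000187). S100a9 had 0.285 ± 0.0803 CPM in castrated males, below what 3 reads are worth, against 204 ± 180 in females (adjusted p = 0.00082), and Sprr2b 0.114 ± 0.161 against 20.4 ± 21.3. BC100530, BC117090, Sprr2d, Car2 and Rps3a3 had log2 fold changes of -5.79, -5.22, -5.46, -4.88 and -5.55. Baiap2l1 stood at 550.4 ± 170 CPM in castrated males and 26.6 ± 8.56 in females (adjusted p = 0.000334), and Stag3, Ogn, Lce1m, Abca4, Flg2, Gpc2 and Golga7b were the other genes with the largest rise in castrated males. Akr1c18 was lowest in castrated males and highest in females (5.58 ± 0.962 against 99.1 ± 21.8 CPM, adjusted p = 0.000183). In all, 266 genes were called, 88 higher and 178 lower in castrated males, with 3332 at an unadjusted p below 0.05. Of these, 219 were also called between females and intact males, a comparison with the same female libraries, so that an overlap arises without shared changes.

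Wound genes fell in 8 of 16 measured, Krt6a, Krt6b, S100a8, S100a9, Sprr2d, Sprr2h, Tnc and Lcn2, with 11 lower and 1 higher adjusted over the list alone (median -2.15, camera adjusted p = 2.45e-10). The median was -1.36 without female replicate 2 in castrated_male against female. Of 35 mitosis genes Aurka fell and 27 did adjusted over the list alone (median -0.71, camera adjusted p = 3.5e-15). Kif2c and Ccnb2 did not pass over all genes (adjusted p = 0.062 and 0.0609). Glycolysis genes had Pfkfb3 called, 17 lower and 1 higher adjusted over the list alone and a median of -0.82 (camera adjusted p = 7.35e-09). Of 31 oxidative phosphorylation genes Sdhd, Cox8a, Ndufa1 and Uqcrq fell, and 26 did adjusted over the list alone (median -0.50, camera adjusted p = 2.1e-15). Frem2, Col4a6 and Fras1 rose among 24 basement membrane genes, 13 rose and 4 fell adjusted over the list alone (median 0.52, camera adjusted p = 0.00139), Ciart rose among 17 clock genes, 9 adjusted over the list alone (median 0.59, camera adjusted p = 2.41e-06), and Ptpn14 among 25 YAP and TEAD targets, 5 adjusted over the list alone (median 0.30, camera adjusted p = 0.00138). H2-Aa, H2-Ab1, Cd74, Ciita, H2-DMb1 and H2-DMa fell among 19 Langerhans and dendritic cell markers, with 7 lower and 1 higher adjusted over the list alone (median -0.29, camera adjusted p = 0.000902). S100a8 and S100a9 fell among 5 macrophage and neutrophil markers, 3 adjusted over the list alone (median -1.36, camera adjusted p = 0.000319). These lists had adjusted p = 0.469 with an estimated correlation. Deviations by transcript length ran in opposite directions in female replicate 2 (Spearman rho -0.264) and castrated male replicate 1 (0.25). Part of the oxidative phosphorylation, ribosomal protein and basement membrane shifts against females may therefore follow length. With the length trend removed, the 42 list calls of the 3 comparisons were kept.

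S phase (median -0.34), ribosomal protein (-0.28), NRF2 (-0.32) and X chromosome genes (-0.49) were also called downward against females (camera adjusted p = 1.16e-05, 1.36e-07, 0.000629 and 1.57e-05). Adjusted over the list alone, 1, 0, 6 and 7 members were lower, and 1 X chromosome gene was higher. With an estimated correlation the camera adjusted p-values were 0.686, 0.617, 0.469 and 0.469. Granular and cornified layer genes were not called (median -0.16, camera adjusted p = 0.956), with Flg2 and Lce1m higher and Rptn lower in castrated males. Krt79, shared by the hair follicle and sebaceous gland lists, and Mgst1 fell (adjusted p = 0.0482 and 0.0481) in lists that were not called (0.059 and 0.494). The estrogen-responsive list was called by fry (adjusted p = 0.0225), as was the X list, and not by camera (0.059), with 0 members called by limma and 4 members lower adjusted over the list alone. The androgen-responsive list, in which Sord rose and Steap4 fell, was not called (median 0.01, camera adjusted p = 0.99). Camera called 13 lists, of which 0 were called with an estimated correlation, and fry called 2, 1 of them among the 13. Without female replicate 2, 38 genes were called, without castrated male replicate 1 or 2, 21 and 30, without female replicate 1, 1323, and without male replicate 1 or 2, 534 and 582. Of 42 named genes that were called, 10 stayed so whichever library was left out: BC100530, Car2, Baiap2l1, Stag3, Akr1c18, Rps3a3, Ddx3y, Eif2s3y, Kdm5d and Uty. S100a8, S100a9, Xist and Tsix were not tested in every such fit. The genes differing among the 3 groups numbered 489 by a joint test, 34 without female replicate 2, 962 without female replicate 1, and 71 and 92 without castrated male replicate 1 or 2.

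The changes in females and in castrated males, both against intact males, were correlated across 14943 genes outside the sex chromosomes (Pearson r = 0.418, genes not being independent). Unchanged groups set against the same males gave r = 0.5 ± 0.0084 over 100 simulations, since both comparisons share their male libraries. The covariance was 0.0873 against a simulated 0.0366, a difference of 0.0507. Of 900 genes called between females and males outside X and Y, 757 (84.1%) had the same sign in castrated males, against 90.1% ± 0.9 simulated. The simulated groups held no change in females, whereas these genes were called there. Neither r nor the same-sign share can therefore be judged against its simulated value. The genes called higher in females had a median log2 fold change of 1.25 there and 0.29 in castrated males, and those called lower -1.05 and -0.26. Of the 6 genes called after castration, 4 were also called in females, a count to which the shared males contribute. The males were not split, as each part would hold 1 library, and part of the excess covariance may come from the shared males.

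**Figure D4:**
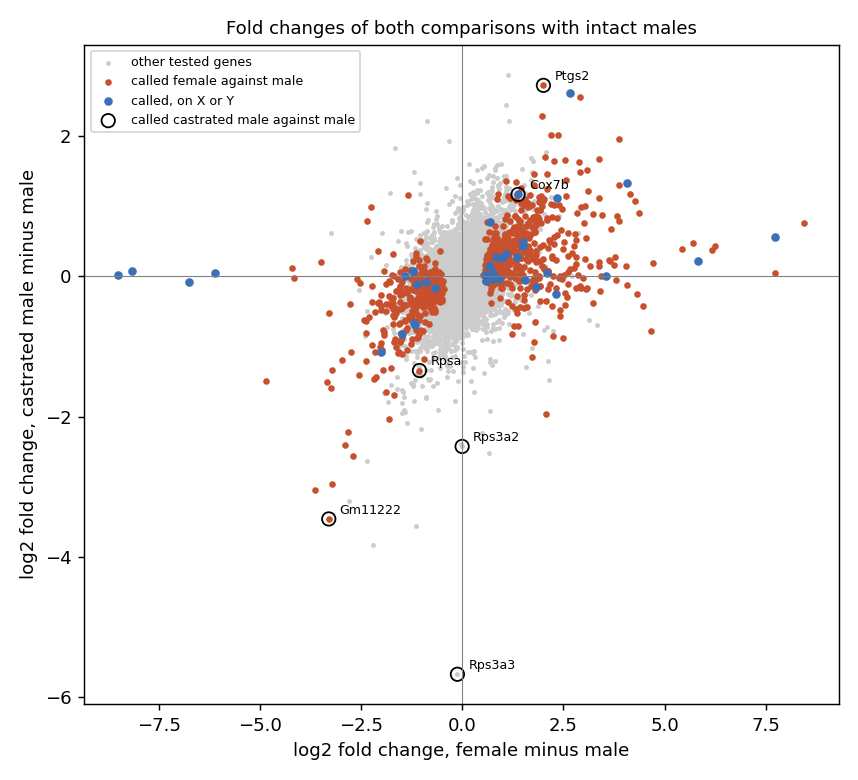
Log2 fold change in castrated males against log2 fold change in females, both relative to intact males, for every tested gene (points), with genes called between females and males coloured and the 6 genes called between castrated and intact males circled. The correlation over genes outside the sex chromosomes was 0.418. Simulated groups without any change gave 0.5, which is no benchmark where females do differ.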

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

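Alternatives in pseudocount, the removal of the length trend and protein-coding genes alone were chosen after the data had been seen, and the others were planned. All counts were within 1.5 times the main counts with median-ratio scaling, library totals, either pseudocount, the length trend removed, without X and Y genes and without markers of other cell types. Of 187 named results, called or not, 187 stayed so with median-ratio scaling, 180 with library totals, 173 with the length trend removed, 159 with the replicate block, 151 with limma-voom, 135 with 2 groups in the fit and 93 to 167 with 1 library left out. In the first 6 of these the others lost their call in the same direction, except 3 that gained one with 2 groups. The genes changed, female against male (940), became 103 with no filter on low values, 265 with 2 groups in the fit, 1992 at an adjusted p below 0.10, 568 with at least 2-fold change, and 49 to 1773 with 1 library left out. The genes changed, castrated_male against male (6), became 2 with no filter, 15 at 0.10, 3 with protein-coding genes and 1 to 74. The genes changed, castrated_male against female (266), became 33 with no filter, 173 at a mean of at least 5 CPM, 88 with limma-voom, 560 with 2 groups, 849 at 0.10 and 21 to 1323. The genes differing among the 3 groups (489) numbered 42 with no filter, 303 at 5 CPM, 179 with limma-voom, 1214 at 0.10 and 34 to 962. Without the filter 27971 genes entered the test; the cause of the other differences was not tested. Called lists (18, 11 and 13) numbered 0, 0 and 0 with an estimated correlation and 3, 0 and 2 by fry, and in castrated against intact males 7 to 12 with 1 library left out. The shared direction of female against male and castrated_male against male (r = 0.418) ran from 0.329 to 0.555. Among named results with a call in either fit, Esr1 between females and males (0.27) reversed, at -1.2 without male replicate 1, and was 1.72 without male replicate 2. With no call in either fit 13 turned sign, 12 with values of at most 0.37 in size and Esr1 between castrated and intact males, from -0.75 to 0.73 without male replicate 2. A lone library was assumed to vary like the other groups. With the replicate number as a block, 817, 5, 162 and 387 genes were called in the same order, with 19, 12 and 13 lists and r = 0.418. The replicate differences of the groups correlated at r = -0.153, -0.01 and 0.194. With 2 libraries per group these values cannot decide whether the replicate numbers pair the samples. The DESeq2 alternatives were not run, since the deposited values are not counts, although the recovered reads could have entered them. Genes below 1.16 CPM in 5 or more libraries were not tested.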

Other observations

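The genes of this paragraph and the next, and all tests of the 3 patterns below, were chosen after values or results had been seen. Further single genes were higher in females than in males, with no list tested for them, and the list of chemokines, cytokines and alarmins was not called (camera adjusted p = 0.464). Serpinb3a, a serpin of stratified epithelia, stood at 91.4 ± 5.31 CPM in females, 6.23 ± 2.33 in males and 11.3 ± 1.22 in castrated males (adjusted p = 0.000196 between females and males). Il1f9, an interleukin 1 family cytokine, stood at 95.2 ± 42.9 CPM in females and 18.5 ± 8.71 in males (adjusted p = 0.0204), and its relative Il1f6 at 7.85 ± 4.31 in females, with 0.112 ± 0.00776 in males, below what 3 reads are worth. Zc3h12a, which encodes an RNase that limits cytokine mRNAs, Socs3, an inhibitor of cytokine signalling, and Irak3, an inhibitor of interleukin 1 signalling, had log2 fold changes of 2.60 ± 0.31, 1.92 ± 0.18 and 1.69 ± 0.18 (adjusted p = 0.00536, 0.00151 and 0.00382). Ehf, an epithelial transcription factor, Fabp5, a fatty acid carrier, and Postn, a matrix protein, had 2.81 ± 0.26, 3.02 ± 0.34 and 1.61 ± 0.20 (adjusted p = 0.00147, 0.00433 and 0.00685).

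Genes lower in females included neighbours on chromosome 5, for which litter in this outbred stock cannot be separated from sex. Gm15708, a transcript within Baiap2l1, stood at 3.35 ± 0.753 CPM in females and 43.5 ± 14.5 in males, and Gm43720, which overlaps Gpc2 and lies next to Stag3, at 7.04 ± 0.889 and 26.3 ± 4.90 (adjusted p = 0.00116 and 0.00685). The division of reads between these overlapping genes is uncertain, since the strand setting of the counting is not given in the sources used here. Cyp2b10, a xenobiotic-metabolising cytochrome, stood at 52.5 ± 11.7 CPM in females, 172 ± 7.36 in males and 139 ± 8.07 in castrated males (adjusted p = 0.00166). The male libraries differed in Krt13 (11.6 and 157 CPM), Krt19 (9.69 and 123), and in Rps2 (221 and 727) with its pseudogene Rps2-ps13 (248 and 3.17). Of 10484 genes, female replicate 2 had 58 at least 2-fold above and 44 at least 2-fold below all other libraries, male replicate 1 had 18 and 22, male replicate 2 had 8 and 34, and the other 3 libraries 0 or 1.

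The wound list was higher in females than in males (median log2 fold change 2.15). Myeloid cells among the sorted female cells are argued against as the whole source: the summed CPM of 18 other myeloid transcripts, of which 6, among them Cxcr2, Laptm5, Srgn, Il1b and Lyz2, were higher and 3 lower in both female than in both male libraries, rose by at most 2.4% of the rise of S100a8 and S100a9 (24.4 and 35.4 in females, 19.6 and 17.5 in males). The cornified list was about as high in castrated males as in females (median -0.16, quartiles -0.59 and 0.4, or 0 in a first form without the 2 shared members). The wound list was lower in castrated males (-2.15, upper quartile -0.92), so cornified genes can be as high without the wound genes. This does not exclude a larger share of suprabasal cells in females, since the cornified list also rose in females against intact males (median 1.03). A single female library is argued against because 14 of 16 genes were higher in female replicate 1 than in both male libraries, although 15 were higher still in replicate 2. In both female libraries 14 were higher than in both male libraries. The 16.7% that chance gives for both holds for independent genes, and these vary together. Sex may account for the difference, but a larger share of suprabasal cells stays open and litter cannot be separated from sex in this design. Neither sex nor litter was tested as a cause.

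Camera called the oxidative phosphorylation and ribosomal protein lists higher and the basement membrane list lower in females than in males, with 9 of 31 and 0 of 39 genes risen and 7 of 24 fallen, and no call with an estimated correlation, and short transcripts were higher than long ones. With the length trend of every library removed, the medians were 0.37 (standard error 0.052, before 0.47) for oxidative phosphorylation, 0.13 (0.055, before 0.25) for ribosomal protein and -0.48 (0.174, before -0.58) for basement membrane genes. The removed trend thus took away a smaller part of the oxidative phosphorylation and basement membrane medians and much of the ribosomal protein median. Whether the trend alone made these shifts cannot be decided from the remainders. Their standard errors are taken over genes that vary together. The correlation estimated by camera was 0.8938 for oxidative phosphorylation, 0.7122 for ribosomal protein and 0.1678 for basement membrane genes. The lengths also came from the annotation and not from the transcripts present in these cells. A biological difference between the sexes stays open and untested.

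Genes called between castrated and intact males may in part reflect copies. The summed CPM of Rps3a1, Rps3a2 and Rps3a3 differed by a log2 of 0.02 between castrated and intact males, as needed if reads or alleles were divided differently between these copies. For Rpsa and its copies the sum fell by 0.88 on the log2 scale (-0.88), although its copy Rpsa-ps10 had 183 and 57 reads in intact and 601 and 624 in castrated males, which leaves this explanation open for Rpsa. A division of counted reads between copies is argued against for Ptgs2, which had 0 copies, and for Cox7b, whose copies held 0 to 9 reads per library. The sum of Cox7b and its copies rose by 1.17 on the log2 scale, which with so few reads in the copies only repeats the rise of Cox7b. Reads left uncounted could not be seen. For both genes an effect of castration or of litter remains open and untested. Of the 6 genes 5 had a copy, against 43.6% of 498 random genes (Fisher exact p = 0.0918). Gm11222 is one of the 5, and its copy Rpl7l1 held 1509 to 1896 reads per library. A division of reads between these copies was not tested.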
